A study of Mus spretus with 8 samples.

How the data were processed

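Gene expression was measured in livers of male Mus spretus of the inbred SPRET/EiJ strain with 1-colour Agilent microarrays, 1 array per mouse. Of the 8 mice, 4 had eaten feed with p,p'-DDE in corn oil for 30 days (450 mg/kg) and 4 had eaten feed with corn oil alone. The deposited value table was used, with 42957 probes on each of the 8 arrays and values on a log2 scale as the authors normalized them. Per the labels, Cy3-labelled RNA was made from total liver RNA. The scanner, the background correction, the normalization method and any filter are not given in the sources used here. All 8 arrays had nearly the same distribution, with medians from 7.46 to 7.47, and the highest value was 16 on every array. The values were used as deposited, with no further filter, offset or normalization in the comparison itself.

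Probes were joined to genes by the annotation table supplied with the data, in which 33009 probes carried 1 gene symbol and 9948 carried none. The named probes covered 22471 genes, of which 6135 had more than 1 probe. Probe sequences are not given in the sources used here. Several probes of a gene may therefore be repeated spots of 1 sequence, and their agreement is not independent evidence. Symbols in the gene lists were brought to the spelling of that table by hand. For gene lists and named genes, each gene was represented by the probe with the highest mean over all 8 arrays. Probes on the array were designed on reference mouse sequence, so a probe may bind Mus spretus transcripts less well, and probes for closely related genes (Cyp2a, Cyp2b, Cyp2c, Cyp3a, Ugt2b, Gstm and Mup families) may bind several of them. Genome positions were not used here.

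Each probe was tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, DDE against control, with 4 arrays per group and no covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 42957 probes, with a threshold of 0.05. Sets of genes were tested with camera from limma at a preset inter-gene correlation of 0.01, for 37 gene lists with at least 5 measured members, and for 899 mouse Reactome pathways of 10 to 300 measured genes shipped with fgsea 1.28.0. These p-values were adjusted over the lists and over the pathways. Both kinds of set were also tested with a correlation estimated for each set, and the lists with fry, which tests whether a list's genes move, on balance, 1 way and makes no comparison with other genes. Counts of list members were made with p adjusted over all probes and with p adjusted over the list alone.

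The groups, the gene lists, the tests, the alternatives other than those named next and the rule for named genes were chosen before the data were examined. By that rule a gene was named if it was among the 15 largest rises or the 15 largest falls past the threshold with no overlap between the groups, leaving out symbols of predicted or unnamed transcripts. It was also named if it was among the 4 largest changes past the threshold in a list, or had the smallest p in a list with none. Further genes were fixed by name, and some of these are not reported here. The rule gave 111 genes, and any other gene in the text was chosen after its values were seen.

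The signal range was described with rules chosen after the data were seen. The background level of an array was the 0.95 quantile of its probes for olfactory and vomeronasal receptors (1634 probes, stained spots left out), and it lay between 7.55 and 7.81. A fold change is written as a lower bound where any value of the dimmer group lay at or below that level, with such values raised to it, or where any value of the brighter group was close to the top of the scale. Probe positions on the array were taken from the order of the feature numbers. Deviations from the probe's median were correlated between spots in adjacent rows (r across spots from 0.0813 in DDE 1 to 0.612 in control 4), while spots far apart along a row were nearly uncorrelated. A spot was called stained where the median deviation in a window of 7 rows by 5 columns was beyond 0.3 in either direction.

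Alternatives fixed beforehand were quantile normalization, centring on the 75th percentile, leaving out the dimmer part of the probes, an intensity trend with robust variance, array weights, the replicate number as a block, leaving out each array in turn, 1 probe per gene, the mean of a gene's probes, a fold change of at least 1.5, ordinary t statistics, an estimated correlation and fry. Alternatives added after seeing the data were leaving out stained spots, doing so and quantile normalizing the rest, and leaving out control 4 and DDE 4 together. The comparison was also repeated on all 35 splits of the 8 arrays into groups of 4 and 4.

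The procedure was tested on simulated data with 4 arrays per group. Of probes changed by 1, 2, 3 and 4 on the log2 scale (50 each), 58%, 78%, 78% and 88% were called with the right sign, and 3 of 42757 unchanged probes were called. All 3 shifted gene lists and 0 of 34 others were called by camera. The simulated genes were independent of each other, so this does not show how often camera calls lists of correlated genes. In the measured lists the estimated correlation reached 0.348 (Kupffer cells and macrophages). In a simulated stain of 2 on the log2 scale on 1 array, 99.6% of the spots were found, while 0.0146% of the spots outside it were marked. On the real arrays the median excess of bright stained spots ran from 0.373 in DDE 1 to 1.995 in control 4, with 1.115 in control 1 and 0.725 in DDE 4. The simulation therefore does not show how many spots of weaker patches were found. For these arrays, their number limits the precision. The slide and scan of each array are not given in the sources used here, so a difference between slides cannot be separated from the groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.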

Results

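Liver RNA from 8 male Mus spretus mice (SPRET/EiJ, an inbred strain derived from a wild mouse species) was measured on 1-colour microarrays with 42957 probes. The control group had 4 mice fed a standard diet with corn oil, and the DDE group had 4 mice fed the same diet with 450 mg/kg of p,p'-DDE, the persistent breakdown product of the insecticide DDT, for 30 days. Each value below is a log2 signal given as mean ± SD with n = 4 mice per group, unless it is a fold change. Between 40.2% (DDE 4) and 46.9% (DDE 2) of the probes lay above the background level of their array. Stained patches, mostly bright, covered part of every array, from 0.521% of the spots of DDE 1 to 9.50% of those of control 4 and 7.59% of those of DDE 4. In a principal component analysis of 11527 probes above background and free of such patches, the first component held 33.9% of the variance, with the controls between -40.2 and -28.1 and the DDE arrays between 19.8 and 55.6.

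**Figure D1:**
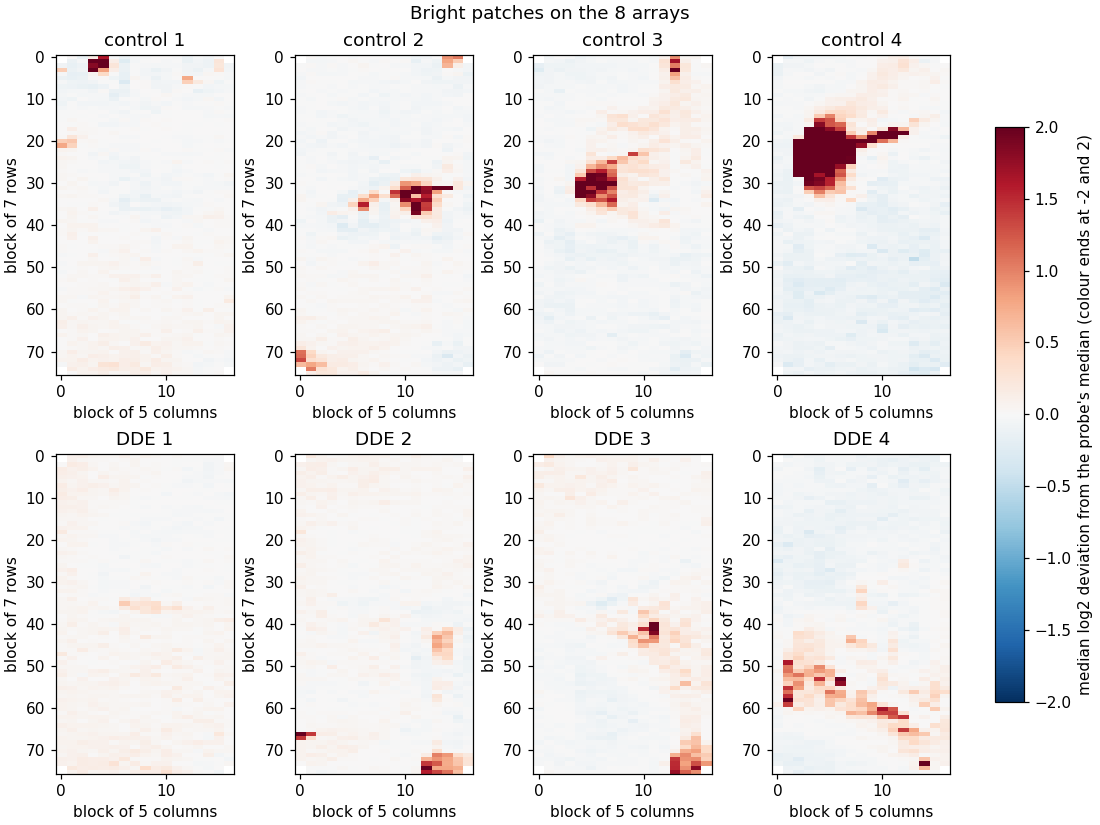
Median deviation (log2) of the spots in each block of 7 rows by 5 columns from the median of the same probe over all 8 arrays, drawn by position on the array, 1 panel per array. Bright patches are widest on control 4, where 9.50% of the spots were marked as stained, and nearly absent on DDE 1 (0.521%).

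The comparison asks which liver genes differed after dietary exposure to p,p'-DDE. Genes of drug metabolism led the rises, and 10 of the 15 largest were in genes fixed beforehand as targets of the receptors CAR and PXR. Cyp2b10, a cytochrome P450 that oxidizes many foreign compounds and a standard target of CAR, went from 9.01 ± 0.37 to 15.97 ± 0.032, at least 124-fold higher because the DDE signal was at the top of the scale (n = 4, limma adjusted p = 2.44e-05). Cyp2c55 rose at least 37.3-fold and Cyp2b9 at least 24.6-fold from control levels at background, and Cyp2a4, a steroid 15-alpha-hydroxylase, rose at least 29.3-fold (10.67 ± 0.83 to 15.55 ± 0.52). The largest fall was in Hsd3b5, a steroid dehydrogenase typical of male mouse liver, which went from 12.16 ± 1.13 to 7.24 ± 0.26, at least 22.7-fold lower and above background in 1 of the 4 DDE livers (adjusted p = 0.00921). All 5 genes stayed past the threshold in each of the 8 fits that left out 1 array.

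Target genes of CAR and PXR, receptors that switch on drug metabolism, rose as a group. Of 50 measured members, 23 rose, 1 fell and 26 did not pass the limma test, or 30 and 2 when adjusted over the list alone. Their median log2 change was 0.92 (camera adjusted p = 1.24e-19, and adjusted p = 0.057 with an estimated correlation), and it was past the threshold in 19 of the 20 alternatives. Besides the Cyp genes above, Akr1c19 rose 9.16-fold and Slco1a4, an uptake transporter for organic anions, 7.69-fold, while Abcc3, an export pump for conjugates, rose 3.42-fold. Cyp2c38 rose at least 11.1-fold at its brightest probe, from 12.35 ± 0.59 to 15.83 ± 0.20, while its other probe changed by -0.84. The 1 member that fell was Sult3a1, with a log2 change of -0.55. Cyp3a11, also a target of PXR, had 15.69 ± 0.11 in controls and 15.35 ± 0.28 after DDE at its brightest probe (adjusted p = 0.344). The control values of this probe, 15.55 to 15.80, left little room for a rise below the top of the scale. The dimmer probe of Cyp3a11 rose by at least 1.23, with 3 of 4 DDE values close to the top of the scale (adjusted p = 0.04). As closely related Cyp2 transcripts can bind each other's probes, the values of single Cyp2a, Cyp2b and Cyp2c genes are uncertain. Cyp2a21-ps, annotated as a pseudogene of the Cyp2a family, gave a signal at least 33.7-fold higher, with 2 of its DDE values close to the top of the scale.

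**Figure D2:**
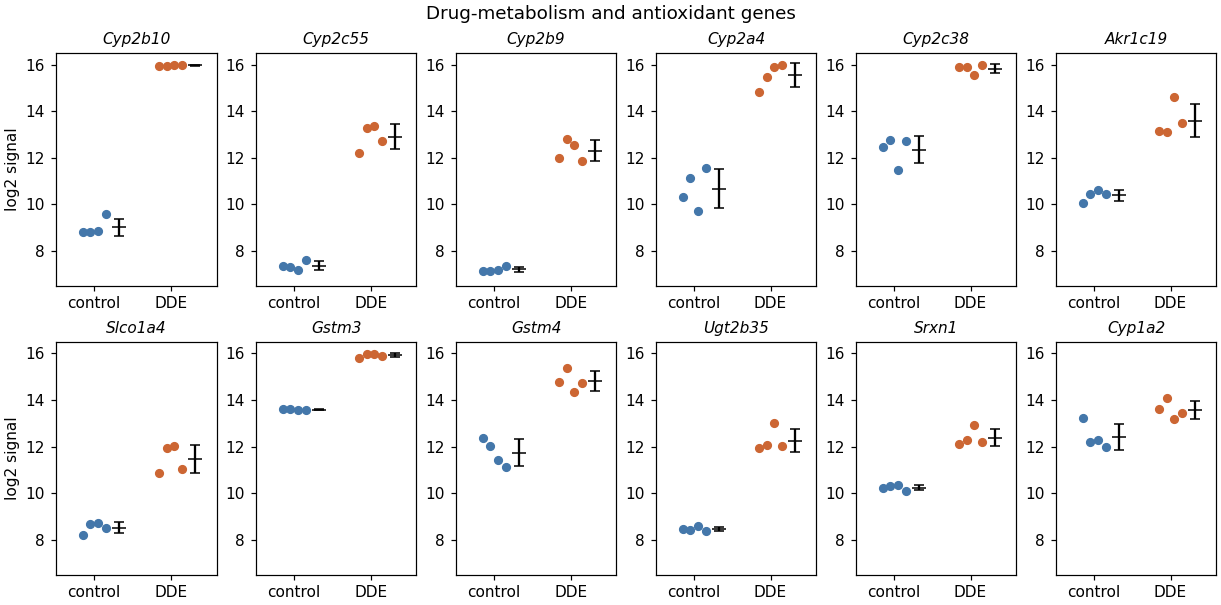
Log2 signal of 12 genes of drug metabolism and antioxidant defence, with 1 dot per mouse and bars for mean ± SD (n = 4 per group). All 4 DDE values lie above all 4 control values in 11 of the panels, and in Cyp1a2, which did not pass the test (adjusted p = 0.117), 1 control value lies among them.

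Conjugating enzymes rose too, but their lists are not separate from that of CAR and PXR. That list also holds the glutathione S-transferases Gsta1, Gsta2, Gstm1, Gstm2, Gstm3, Gstm4, Gstm6, Gstp1, Gstt1 and Gstt3. It holds Ugt1a1, Ugt1a9, Ugt2b34, Ugt2b35, Ugt2b36, Sult2a1 and Sult3a1 as well. Among glutathione S-transferases, which couple glutathione to reactive compounds, 7 of 25 rose and 0 fell, or 13 and 0 when adjusted over the list alone, with 13 higher and 0 lower at an unadjusted p under 0.05. The list had a median change of 0.68 and a camera adjusted p of 3.16e-08 (adjusted p = 0.057 with an estimated correlation, the highest of the 20 alternatives). Gstm3 went from 13.59 ± 0.021 to 15.93 ± 0.078, at least 5.05-fold as 3 of the DDE values were close to the top of the scale (limma adjusted p = 2.44e-05), and Gstm4 rose 8.34-fold. The other probe of Gstm3 changed by -0.43, and with the mean of its probes Gstm3 did not pass (0.95, adjusted p = 0.469, with 9.67e-06 at the lowest of its 18 alternatives, of which 17 passed). Of 26 UDP-glucuronosyltransferases and sulfotransferases, 8 rose and 1 fell, or 11 and 1 when adjusted over the list alone. This list's camera adjusted p was 3.17e-05 (adjusted p = 0.439 with an estimated correlation, and from 1.38e-05 to that value over all alternatives). Ugt2b35 rose 13.8-fold at 1 of its 2 probes (the other changed by 0.01), Ugt2b5 5.21-fold, Ugt2b37 4.28-fold and Ugt2b36 3.85-fold, within a family whose members share much of their sequence. Target genes of the aryl hydrocarbon receptor were not past the threshold as a group (camera adjusted p = 0.375). In it 0 of 11 members passed, against 3 when adjusted over the list alone and 3 at an unadjusted p under 0.05, all higher. Cyp1a2 had 12.43 ± 0.56 in controls and 13.57 ± 0.38 after DDE (adjusted p = 0.117), and Cyp1a1 was above background in 0 of 4 controls and 2 of 4 DDE livers (adjusted p = 0.398), with both of these values on stained spots.

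Antioxidant and proteasome genes were higher as groups. The NRF2 list shares Gsta1, Gsta2, Gstm1, Gstm3, Ephx1 and Abcc4 with the CAR and PXR list. Of 30 NRF2 antioxidant genes, 6 rose and 0 fell, or 8 and 0 when adjusted over the list alone, with 9 higher and 0 lower at an unadjusted p under 0.05. Its camera adjusted p was 0.00158 (adjusted p = 0.398 with an estimated correlation, and from 0.000182 to that value over all alternatives). The 6 were Srxn1, which repairs peroxiredoxins (4.42-fold, limma adjusted p = 0.00586), Gstm3, Me1 (4.08-fold, at 1 of its 3 probes), Cat, the gene of catalase (2.82-fold), Gsr, the gene of glutathione reductase, and Pgd of the pentose phosphate pathway (1.85-fold). Nqo1, a common marker of NRF2 activity, had 8.81 ± 0.31 in controls and 9.73 ± 0.48 after DDE and did not pass (adjusted p = 0.133). In the proteasome list 4 of 40 members rose and 0 fell, or 13 and 1 when adjusted over the list alone, with 19 higher and 1 lower at an unadjusted p under 0.05. Psmd8 rose 2.61-fold, Psme1 2.55-fold, Psmc4 2.22-fold and Psmd5 2.04-fold. Of the 10 probes of Psme1 only this 1 passed, with a median change of 0.86 over all 10. The list's camera adjusted p was 3.28e-06 (adjusted p = 0.677 with an estimated correlation, 0.0541 with fry, and past the threshold from 7.52e-07 upward in the other 18 alternatives).

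Genes that differ between the sexes in mouse liver changed in both lists. Of 35 female-biased genes, 6 rose and 1 fell, or 10 and 1 when adjusted over the list alone (camera adjusted p = 0.00403, and adjusted p = 0.447 with an estimated correlation, against 0.0005 at the lowest of all alternatives). The 6 were Cyp2b9 and Cyp2a4, which are also on the CAR and PXR list, Cyp2c39 (at least 4.98-fold), Cyp3a41b (4.21-fold), the fatty acid transporter Cd36 (4.06-fold) and Fmo1. Cyp3a41b had 3 stained spots and did not pass after stained spots were left out and the rest renormalized (1.29, adjusted p = 0.102, with 0.0203 to 0.221 over all alternatives). Among 32 male-biased genes, 4 fell and 3 rose, or 7 and 6 when adjusted over the list alone, and the median change was -0.36. The list passed as lower (camera adjusted p = 0.0163, and adjusted p = 0.742 with an estimated correlation), except without control 3 (adjusted p = 0.0519), with array weights (0.062) and with fry (0.448), and its lowest adjusted p was 0.000963. Hsd3b5, Nudt7 (a peroxisomal coenzyme A hydrolase), Elovl3 (an elongase of very long fatty acids) and Cyp2u1 fell. Elovl3 went from 11.42 ± 0.40 to 9.14 ± 0.65 (adjusted p = 0.0238) and Nudt7 from 14.41 ± 0.70 to 11.66 ± 0.94 (adjusted p = 0.0449). The 3 that rose were Ugt2b38 (3.83-fold), Cyp2d9 and Cyp4a12a. Of the major urinary proteins, Mup20 had 2 probes with 15.98 ± 0.016 and 15.20 ± 0.81 in controls and 15.75 ± 0.38 and 13.34 ± 1.17 after DDE, neither past the threshold (adjusted p = 0.631 and 0.223). All 4 control values of the brighter probe were close to the top of the scale, so a fall there may be larger than measured.

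**Figure D3:**
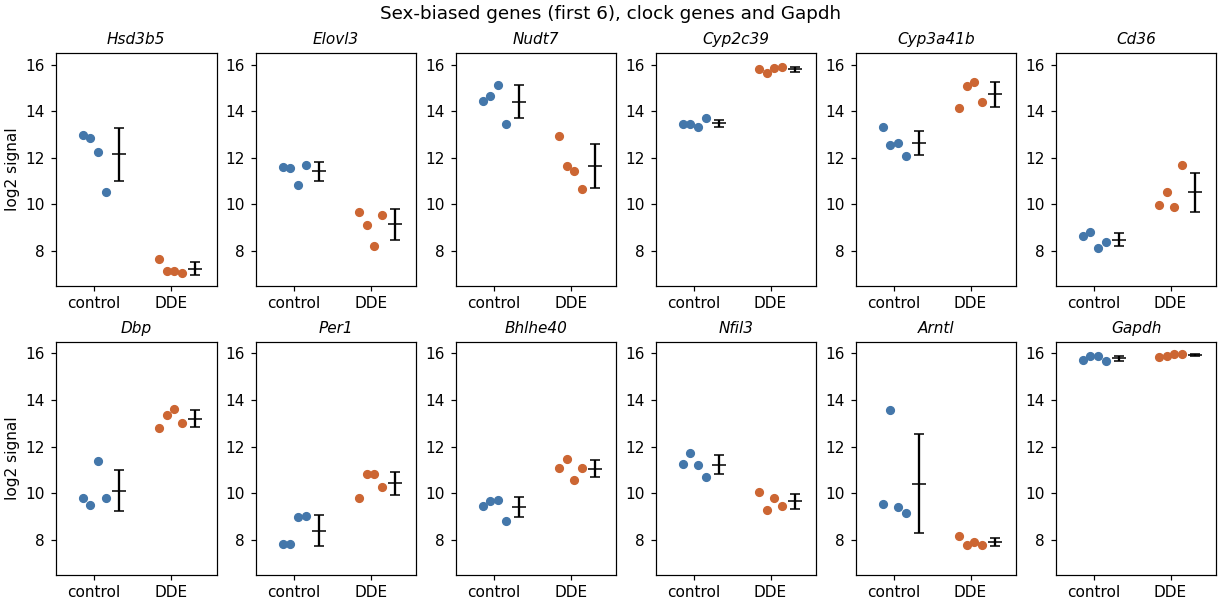
Log2 signal of 6 sex-biased liver genes, 5 clock genes and Gapdh, with 1 dot per mouse and bars for mean ± SD (n = 4 per group). Hsd3b5 went from 12.16 to 7.24 and Dbp from 10.12 to 13.19, and 1 control mouse at 13.58 widens the spread of Arntl.

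Lipid genes moved in more than 1 direction. Of 46 genes of PPARalpha and fatty acid oxidation, 4 rose and 1 fell, or 10 and 2 when adjusted over the list alone. Those that rose were Vnn1 (4.52-fold), Cd36, Fitm1 (2.19-fold) and Cpt1a, the entry step of mitochondrial fatty acid oxidation (2.03-fold at 1 of its 11 probes, with a median change of 0.61 over all 11), and Cpt1b fell at least 1.35-fold. The list had a camera adjusted p of 0.0163 (adjusted p = 0.704 with an estimated correlation), and its call was lost without control 1 (adjusted p = 0.0746), without the dimmer probes (0.0527) and with fry (0.0541), with 0.000921 at the lowest. Cyp4a14, a sensitive PPARalpha target, stayed near background with 7.37 ± 0.12 in controls and 7.62 ± 0.25 after DDE. Lipoprotein genes were lower as a list, with 3 of 27 fallen and 0 risen, or 5 and 1 when adjusted over the list alone, and 6 lower and 3 higher at an unadjusted p under 0.05. The camera adjusted p was 0.0174 (adjusted p = 0.704 with an estimated correlation), and the call was lost without control 3 (adjusted p = 0.0519), without DDE 4 (0.0704), with array weights (0.0691), with the mean of a gene's probes (0.0686), without control 4 and DDE 4 (0.0788) and with fry (0.204), with 0.00521 at the lowest. Apob, the scaffold of very low density lipoprotein, fell from 15.65 ± 0.23 to 13.91 ± 0.31, 3.33-fold (limma adjusted p = 0.00887), while Apoh fell at least 1.80-fold and Apoa1 at least 1.52-fold. Of Apoa1's 10 probes only this 1 passed, and all 10 had lower means after DDE.

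Fat synthesis did not pass as a group (camera adjusted p = 0.871). In it 6 of 41 genes rose and 2 fell, or 7 and 7 when adjusted over the list alone. Me1, Tkfc (2.95-fold) and Scd2 (2.91-fold) rose and Elovl3 fell, whereas Fasn had 11.67 ± 0.46 in controls and 11.25 ± 0.54 after DDE and Scd1 14.80 ± 0.81 and 15.10 ± 0.30, neither past the threshold (adjusted p = 0.633 and 0.711). In cholesterol synthesis and uptake 1 of 22 fell, Ebp (2.32-fold), and 0 rose, the same when adjusted over the list alone, with 4 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.463). Among 30 genes of bile acid synthesis and transport, 3 rose (Slco1a4, Abcc3 and Nr1h4, the bile acid receptor) and 1 fell (Slco1b2, 1.73-fold), or 6 and 3 when adjusted over the list alone (camera adjusted p = 0.73). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 9.60 ± 0.41 in controls and 9.89 ± 0.50 after DDE (adjusted p = 0.64).

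Glycolysis and the pentose phosphate pathway passed as higher, with 2 of 30 members risen and 1 fallen, or 9 and 2 when adjusted over the list alone. Pfkl, the liver phosphofructokinase, rose 1.92-fold and Pgd 1.85-fold, and Eno3 fell 2.19-fold. The camera adjusted p was 0.0268 (adjusted p = 0.447 with an estimated correlation), and it was 0.115 after stained spots were left out and the rest renormalized, 0.0519 without control 3, 0.0584 without control 4 and 0.0923 without DDE 4, with 10 of all 20 alternatives past the threshold and 0.013 at the lowest. For gluconeogenesis and glycogen, 1 of 33 rose (Gpt2, 1.73-fold) and 2 fell (Irs2, 3.36-fold, and Got1, 2.44-fold), or 3 and 4 when adjusted over the list alone (camera adjusted p = 0.375). Pck1 had 13.22 ± 0.83 in controls and 13.28 ± 0.36 after DDE, and G6pc 14.33 ± 0.98 and 13.45 ± 0.69 (adjusted p = 0.954 and 0.554). In the tricarboxylic acid cycle 1 of 28 rose, Suclg2 (3.19-fold), and 0 fell, or 4 and 0 when adjusted over the list alone, with 4 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.463). Of 75 respiratory chain genes 0 passed, also when adjusted over the list alone, with 10 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.728), and the smallest p was that of Sdhd (0.94, adjusted p = 0.1). In amino acid catabolism and the urea cycle 1 of 38 rose, Shmt2 (3.06-fold), and 2 fell, Got1 and the glutamine synthetase gene Glul (2.24-fold), or 8 and 3 when adjusted over the list alone (camera adjusted p = 0.871).

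Clock genes included 3 that rose and 1 that fell among 22, or 5 and 3 when adjusted over the list alone. Dbp, an output gene of the daily clock, went from 10.12 ± 0.86 to 13.19 ± 0.37, 8.44-fold (limma adjusted p = 0.0178), and its other probe rose as well. Per1 rose 4.08-fold and Bhlhe40 3.11-fold, and Nfil3, which represses many Dbp targets, fell 2.96-fold. The list missed the threshold in camera (adjusted p = 0.186), passed it with fry (0.0348) and passed it in camera after stained spots were left out and the rest renormalized (0.0325), with 0.0207 to 0.704 over all alternatives. Hepatic stress lists did not pass. For endoplasmic reticulum stress, Trib3 (2.83-fold) and Ddit3 (at least 1.56-fold, above background in 2 of 4 controls) rose and 0 of 33 fell, or 3 and 1 when adjusted over the list alone, with 5 higher and 4 lower at an unadjusted p under 0.05 (camera adjusted p = 0.375). For heat shock proteins 0 of 20 passed, also when adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.728), and Hspd1 had the smallest p (-0.54, adjusted p = 0.172). Of 34 p53 targets and apoptosis genes, Gadd45b (3.73-fold) and Mcl1 (2.40-fold) rose and 0 fell, or 5 and 1 when adjusted over the list alone, with 7 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.674).

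Lists of inflammation and cell division did not pass as groups. In the acute phase list 2 of 30 rose, Orm3 (at least 9.76-fold, above background in 2 of 4 controls) and Crp (1.32 on the log2 scale), and 1 fell, Itih3 (-1.32), or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.968). Of 35 cytokine and signalling genes 1 rose, Relb (at least 1.79-fold, above background in 1 of 4 controls), and 0 fell, or 2 and 0 when adjusted over the list alone, with 5 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.427). For the interferon response 0 of 38 passed, also when adjusted over the list alone, with 3 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.375, with 0.0198 without control 4 and up to 0.904 over all alternatives), and Ifi27l2a had the smallest p (0.81, adjusted p = 0.0764). In the cell cycle list 1 of 44 rose, E2f1 (at least 1.18-fold, with all controls at background), and 0 fell, also when adjusted over the list alone, with 10 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0938, with 0.0339 without control 1 and up to 0.704 over all alternatives). Mki67, a marker of dividing cells, had 7.82 ± 0.24 in controls and 8.17 ± 0.20 after DDE (adjusted p = 0.34).

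Iron and metal handling showed single changes. Of 27 heme and iron genes 3 rose, namely Blvrb, the biliverdin reductase B gene (3.64-fold), Tfrc, the transferrin receptor (2.86-fold), and Ppox of heme synthesis (2.83-fold), while Tfr2 fell 1.51-fold, or 6 and 2 when adjusted over the list alone (camera adjusted p = 0.382). Among 22 metallothionein and metal transport genes, the zinc importer Slc39a4 rose 2.51-fold and the zinc exporter Slc30a1 fell 1.55-fold, or 1 and 1 when adjusted over the list alone (camera adjusted p = 0.931). Of 46 genes of steroid metabolism and nuclear receptors, 2 rose and 1 fell, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.728). These were Nr1h4 (1.65-fold), Nr1i2, the gene of PXR (at least 1.43-fold, above background in 1 of 4 controls), and Hsd3b5.

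Markers of other cell types and tissues were examined in the same way. The list for pancreas, fat, muscle and gallbladder passed as lower with 1 of 31 members fallen, the muscle myosin Myh1 (3.35-fold), and 0 risen, the same when adjusted over the list alone, with 3 lower and 0 higher at an unadjusted p under 0.05. Its camera adjusted p was 0.0067 (adjusted p = 0.704 with an estimated correlation), and it missed the threshold without control 1 (0.059), without control 4 (0.0584), without DDE 2 (0.0826) and with fry (0.448), with 4.81e-06 at the lowest, without control 2. Single arrays stood far apart in this list, and the lowest median was that of a control (-1.54 in control 2, followed by -1.25 in DDE 2). Of 27 hepatocyte genes, Nr1i2 rose and Apob, Apoh and Apoa1 fell, the same counts of 1 and 3 when adjusted over the list alone (camera adjusted p = 0.193), and Alb was close to the top of the scale in both groups (15.97 ± 0.053 and 15.98 ± 0.0096). In the fibrosis and stellate cell list Tgfbr1 (1.43-fold, at 1 of its 2 probes) and Reln (above background in 0 of 4 controls and 2 of 4 DDE livers) rose and the fibronectin gene Fn1 fell 3.01-fold, or 3 and 2 of 39 when adjusted over the list alone (camera adjusted p = 0.492), and Col1a1 had 8.78 ± 0.38 and 9.40 ± 0.13 (adjusted p = 0.152). For 25 endothelial genes Flt4 rose (at least 1.45-fold, with all controls at background) and 0 fell, or 1 and 0 when adjusted over the list alone, with 3 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.463). Of 15 red blood cell genes Tfrc rose and 0 fell, or 1 and 0 when adjusted over the list alone, with 3 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.728).

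In the lists for Kupffer cells and macrophages, lymphocytes and neutrophils, and cholangiocytes, 0 of 28, 0 of 30 and 0 of 17 genes passed the limma test, also when adjusted over the list alone. At an unadjusted p under 0.05 they held 1, 1 and 1 higher and 3, 2 and 0 lower. Their camera adjusted p were 0.375, 0.375 and 0.327. The macrophage list passed as lower after stained spots were left out and the rest renormalized (adjusted p = 0.014, median -0.24, with 0.0109 to 0.967 over all alternatives), where 3 of its genes fell. The smallest p belonged to Lyz1 (-1.05 with an adjusted p of 0.169), Elane (-1.84 with 0.0814) and Pkhd1 (0.35 with 0.255). Over the 26 lists that did not pass, 34 memberships rose and 17 fell of 810 measured. In 7 of those lists the median, the mean and the test differed in sign, and in 0 of the 11 that passed.

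**Figure D4:**
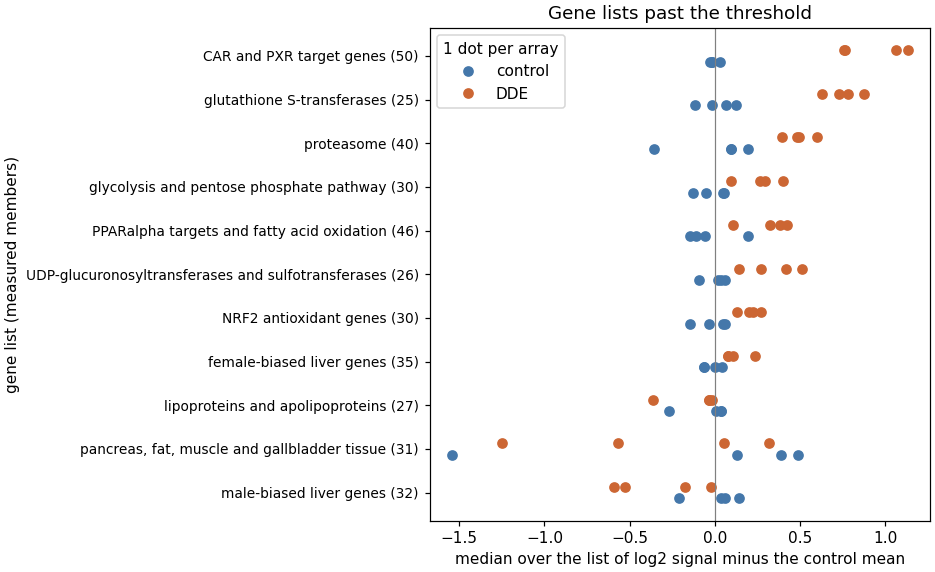
Median over each gene list of the log2 signal minus the control mean of the same gene, with 1 dot per array for the 11 lists past the threshold and the number of measured members in brackets. In the CAR and PXR list the 4 DDE arrays lie between 0.76 and 1.13, apart from the 4 controls, while the dots of the 2 groups overlap in the lists for pancreas, fat, muscle and gallbladder, for lipoproteins, for male-biased genes and for PPARalpha.

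Of the other genes with the largest changes, Chil1, a chitinase-like protein, rose at least 59.5-fold from background in all 4 controls to 13.57 ± 2.14, with a spread among the DDE livers from 10.51 to 15.49 (adjusted p = 0.0248). Inmt, a methyltransferase, rose 13.4-fold and Rarres1 8.01-fold. Cyp2c68 and Cyp2c67 fell 5.50-fold and 5.01-fold while Cyp2c38 and Cyp2c55 rose, so probes for the Cyp2c family went both ways. After stained spots were left out and the rest renormalized, the probes of Cyp2c38 itself were called in both directions. The mitochondrial ND6 probe (at least 5.67-fold), Nkd2 (5.32-fold), Adgrv1 (at least 5.24-fold), Rnu1b6 (5.21-fold), Macroh2a2 (5.14-fold), Ncoa5 (4.71-fold), Rapsn (at least 4.52-fold), Tmc5 (4.29-fold), Igfbp2 (4.26-fold) and Ang3 (4.16-fold) made up the rest of the 15 largest falls. Of Nkd2, Adgrv1 and Tmc5 only 1 of 2 probes fell, and the other changed by -0.08, -0.05 and -0.17. ND6 was above background in 2 of 4 DDE livers. Gapdh, often used as a reference gene, had 15.80 ± 0.11 and 15.93 ± 0.053 at its brightest probe, close to the top of the scale, while 4 of its 7 probes rose.

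In an unselected collection of 899 Reactome pathways, 136 passed the threshold in camera, 127 higher and 9 lower. Glutathione conjugation had 6 of 27 genes risen and 0 fallen (adjusted p = 7.98e-06), and the pathway of xenobiotics 10 risen and 2 fallen of 37 (adjusted p = 0.000147). Biological oxidations had 23 risen and 6 fallen of 167 (adjusted p = 0.000816). Of the 136, 70 held 20 or more of the proteasome genes and 66 held none. Lower pathways included striated muscle contraction (0 of 31 risen and 1 fallen, adjusted p = 0.000135) and the complement cascade (0 of 24 risen and 1 fallen, adjusted p = 0.0037). With an estimated correlation 0 of the 899 pathways passed (adjusted p = 0.925 for each pathway named here, with 18 at an unadjusted p under 0.05 against 257 with the preset value) and 0 of the 37 lists (4 at an unadjusted p under 0.05, and 7 with fry). Leaving out the dimmer probes gave 84 pathways.

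Over all probes, 1005 were higher and 284 lower after DDE at a limma adjusted p under 0.05, so that 78.0% of the calls were higher. In terms of genes, 579 were higher and 174 lower at their brightest probe, and 202 of the 1289 called probes had no symbol. After stained spots were left out and the rest renormalized the counts were 1504 and 1089, with 58.0% higher, and 1151 of the 1289 calls were shared in the same direction, with 0 of the 1289 opposite in sign. The median log2 change of the probes above background was 0.098 as deposited and 0.012 after that renormalization. The groups did not overlap in any of the 1289 called probes, nor in 11.8% of all probes, where chance gives 2.86%. A fold change of at least 1.5 was reached by 915 and 252 of the calls. Leaving out 1 array gave 654 and 128 without control 1, 321 and 66 without control 2, 444 and 90 without control 3, 765 and 428 without control 4, 408 and 97 without DDE 1, 271 and 61 without DDE 2, 455 and 78 without DDE 3, and 1362 and 234 without DDE 4. Without control 4 and DDE 4, the arrays with the most stained spots, 1265 probes were higher and 443 lower. An intensity trend with robust variance gave 399 and 112, array weights 1607 and 533, and ordinary t statistics 424 and 95. The replicate number as a block gave 8 and 1.

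Among the 111 named genes, 61 rose, 30 fell and 20 did not pass. In the 8 fits without 1 array no sign of the 91 that passed could turn, because the groups did not overlap in any called probe. Of the 91, 34 stayed past the threshold in all 8 fits, among them Cyp2b10, Cyp2b9, Cyp2c55, Cyp2a4, Gstm3, Gstm4, Ugt2b35, Slco1a4, Srxn1, Hsd3b5 and Apob. Ddit3 and Tfr2 passed in 0 of the 8. Dbp and Elovl3 passed in 5 of them, Chil1 in 3, and Per1, Cd36 and ND6 in 1. The number that stayed past the threshold was 53 without control 1, 38 without control 2, 44 without control 3, 77 without control 4, 51 without DDE 1, 37 without DDE 2, 46 without DDE 3 and 74 without DDE 4. After stained spots were left out and the rest renormalized 85 of the 91 stayed past it, and Cyp3a41b, Scd2, Trib3, Per1, Tgfbr1 and E2f1 did not. With the mean of a gene's probes Gstm3, Cpt1a, Psme1, Adgrv1 and Tgfbr1 did not pass. With the replicate number as a block 3 of the 91 stayed past the threshold. The others missed it by differing margins, with a limma adjusted p of 0.0541 for Cyp2b9 and Ugt2b35 and 0.0911 for Glul. Of the 91, 24 had more than 1 probe, and in 17 of these 1 probe alone passed.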

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

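The tests of the bright patches, of stained spots in clock genes, of Xist and of Y-linked genes were chosen after the results they bear on were seen, as were the limit of the clock test to genes above background and its repeat without the called genes, while the tests of clock phase, gene families and splits of the arrays were chosen before.

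More probes were higher than lower after DDE, 1005 against 284 (78.0% higher). With bright patches and the normalization across arrays as the explanation, the share should move at least halfway to even, and it fell to 58.0% once stained spots were left out and the rest renormalized, although both counts grew there, to 1504 higher and 1089 lower. Leaving out stained spots alone gave 77.3% and quantile normalization alone 77.8%, so either step by itself moved the share little. The fit without control 4, the array with the most stained spots, gave 64.1% with neither step (74.1% without control 4 and DDE 4). Leaving out DDE 4, the DDE array with the most stained spots, gave 85.3%. The fits without 1 of the other arrays gave 80.8% to 85.4%. The prediction was met with both steps together. However, the lower calls grew by more than the higher ones, and 58.0% of the calls were still higher. The share therefore cannot tell how much of the excess was a distortion by the patches and how much was real. With the arrays taken as unpaired, chance can be excluded for the count of higher probes at 5%. The real split alone of 35 gave 1005 and the highest of the others gave 1. Pairs by replicate number would leave too few exchanges of arrays to reach 5%. With that number as a block, 8 probes were higher and 1 lower. How much of the excess was caused by DDE stays open, as the slides are not given in the sources used here.

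Dbp, Per1 and Bhlhe40 rose and Nfil3 fell together. A difference in the phase of the daily clock between the groups could come, for instance, from the hour at which livers were taken. It predicts that most phase-marked genes lie in 1 direction, with a mark of at least 80% of those measured fixed beforehand. Of 15 measured, 12 (80%) did so on the deposited values and 14 after renormalization, which meets that mark. Of the 10 above background 8 (80%) did so on the deposited values and 10 after renormalization, or 5 and 7 of the 7 that were not called. The 7 are too few to decide without the called genes, and the hour of sampling is not given in the sources used here. A phase difference and an effect of DDE therefore cannot be told apart. Stained spots under these genes are argued against, since 0 of the 32 values of the 4 lay on one, but Per1 did not pass after renormalization, where its change went from 2.03 (SE 0.387) to 1.83 (SE 0.446, adjusted p = 0.0579, with 0.0284 to 0.125 over all alternatives), smaller and less precise. A direct effect of DDE on the clock was not tested.

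The list of male-biased genes passed as lower and that of female-biased genes as higher, with 4 of 32 fallen and 3 risen in the first and 6 of 35 risen and 1 fallen in the second. The labels give males, and whether females were among the DDE mice cannot be told from the values. Xist reached 7.2 at most on a DDE array (lowest DDE background level 7.55), but no female liver was there to show that the Xist probes work in Mus spretus. The Y-linked Eif2s3y lay above background on all 8 arrays (8.76 to 10.93). Of the Y-linked Uba1y, 1 probe did so on 4 control and 3 DDE arrays and the other on 2 and 3. On the other side, the Y-linked Zfy1 fell from 9.31 ± 0.49 to background in all 4 DDE livers (limma adjusted p = 0.0119). Kdm5d, Sry, Usp9y, Uty and Zfy2 lay above background on at most 1 control array and cannot tell. Cross-hybridization within gene families as the whole cause predicts that the median turns its sign without those families. Without them 12 male-biased genes had a median of -0.60 (camera adjusted p = 0.0118 over both tests, 2 fallen and 0 risen), and 16 female-biased genes, also without the CAR and PXR list, had a median of 0.14 (camera adjusted p = 0.0217, 2 risen and 0 fallen). Neither sign turned, which argues against that cause at the preset correlation only. An estimated correlation was not run on the remaining genes, and at the preset value at least 1 list passed in 28 of the other splits. A shift of the liver toward the female pattern in DDE-fed males is a hypothesis that stays open, with the calls lost under an estimated correlation (adjusted p = 0.742 and 0.447).

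Of the 35 splits, only the real 1 gave as many as 11 called lists, with 8 as the highest of the others. With the arrays taken as unpaired, chance can be excluded for that count at 5%. The same holds for the 284 lower probes (1 of 35, with 1 as the highest of the others). For the Reactome count chance cannot be excluded, because 3 of the 35 splits gave 136 or more, and the highest of the others gave 189. Both of the others put DDE 4 with control 3 and control 4, which points to a structure among the arrays beyond the groups. Lists passed in 28 of the 34 other splits, with a median of 3.5 lists.

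Single mice stood apart from their group by Dixon's test in 21 of 228 groups of 4 values, and chance flags about 1 in 20 groups. In the control group, Ang3 was 10.68 in control 4 (others 11.81 to 11.99), Eno3 10.66 in control 4 (others 11.20 to 11.27) and Cyp2b10 9.57 in control 4 (others 8.79 to 8.87). The mean correlation of control 4 with the other controls was 0.798, against 0.865 to 0.877 for the others, and 0.948 for control 4 once stained spots were left out. Cyp4a14 was 7.54 (others 7.30 to 7.32) and Gstm6 9.39 (others 9.06 to 9.09) in control 2. Dbp was 11.39 (others 9.49 to 9.80), Elovl3 10.82 (others 11.57 to 11.68) and Psmc4 10.96 (others 10.80 to 10.82) in control 3. Mki67 was 8.18 in control 1 (others 7.65 to 7.74).

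In the DDE group, Cyp2a21-ps was 14.5 (others 15.82 to 16), Hsd3b5 7.63 (others 7.06 to 7.13) and Orm3 10.26 (others 11.42 to 11.55) in DDE 1. In DDE 2, Slc39a4 was 14.13 (others 13.71 to 13.77), Ugt2b36 14.5 (others 14.26 to 14.29) and Suclg2 12.57 (others 11.55 to 11.66), the last on a stained spot. In DDE 3, Itih3 was 13.71 (others 14.36 to 14.41), Scd1 15.55 (others 14.92 to 15.02) and Ugt2b35 13.01 (others 11.93 to 12.07). In DDE 4, Apoh was 14.54 (others 15.08 to 15.18) and Pkhd1 8.52 (others 8.85 to 8.91).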

How the results depend on the processing

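Leaving out stained spots, with or without renormalization, and leaving out control 4 with DDE 4 were chosen after seeing the data, and all other alternatives before. Of the named genes, 91 of the 91 past the threshold kept their sign under each alternative that valued them. In fits that only left out arrays or spots no sign could turn, because the groups did not overlap in any called probe. The 11 gene lists kept their direction everywhere. Quantile normalization and centring on the 75th percentile left 90 of the 91 genes and all 11 lists past the threshold. Where a count moved by over 1.5 times the cause was not tested, except that fewer probes or arrays entered some fits. With an intensity trend and robust variance 399 probes were higher and 112 lower, with array weights 1607 and 533, with 1 probe per gene (fewer tests) 588 and 178, and with ordinary t statistics 424 and 95. With the replicate number as a replicate block the counts were 8 and 1, with 10 lists and 3 of the 91 genes kept. As signals, control and DDE arrays correlated by 0.732 to 0.952. To compare arrays by number, the group mean was first subtracted from each probe above background. Across these probes, the deviations of arrays that share a number correlated by 0.0907, 0.0273, 0.0435 and -0.0098 for numbers 1 to 4. With stained spots left out, these deviations correlated by 0.167, 0.115, 0.12 and -0.0473. The array of the same number was the best partner for numbers 1 to 3 and not for number 4. For that reason the arrays were not taken as pairs. The stained share also rose with the number in both groups, from 1.16% to 9.50% in controls and from 0.521% to 7.59% in DDE. With the partners of 1 to 3 this is a hint that arrays of 1 number share more than the number, and pairing is left open. The counts over splits of the arrays take them as unpaired too, and the block takes up degrees of freedom. After stained spots were left out and the rest renormalized 1089 probes were lower, and without control 4 and DDE 4 443. Leaving out the dimmer probes gave 84 Reactome pathways. An estimated correlation gave 0 lists and 0 pathways (4 and 18 at an unadjusted p under 0.05), and fry gave 7 lists. Over the 8 fits without 1 array the counts ranged from 271 (without DDE 2) to 1362 (without DDE 4) for higher probes, from 61 (without DDE 2) to 428 (without control 4) for lower probes, from 8 to 11 for lists and from 105 to 177 for pathways. The scale alternative log2(value + 1) was not run because the deposited values are already on a log2 scale. Signal over background limits the rest: 18109 of 42957 probes lay above background on at least 4 arrays.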

Other observations

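The genes in this part were chosen after their values were seen. Hao2, a hydroxyacid oxidase of peroxisomes, has 10 probes on the array, of which 8 rose from controls at background, 7 of them by at least 3.15-fold to 3.71-fold. The rise at the other of the 8 had 2 stained spots among its values and was smaller than those of the 7 after stained spots were left out and the rest renormalized. All 10 had higher means after DDE, while the probe that stood for Hao2 in the female-biased list did not pass (adjusted p = 0.16) and had 1 stained spot. The probes of Hao2 share 1 accession, as do those of Slc25a4 and those of Tfrc below, and in DDE 1 the Hao2 values lay between 8.49 and 8.94. They may be repeated spots of 1 sequence. Slc25a4, the ADP/ATP carrier of the inner mitochondrial membrane, also has 10 probes. All 10 were lower, from -2.01 to -0.79, and 4 of them fell past the threshold (6 after stained spots were left out and the rest renormalized). Of the 12 probes of Tfrc, the transferrin receptor, 10 rose. Alas1, the first enzyme of heme synthesis and a CAR target, had 12.99 ± 1.44 in controls and 15.54 ± 0.28 after DDE at its brighter probe (n = 4, limma adjusted p = 0.105). The value of control 3 there, 14.66, came from a stained spot, and after stained spots were left out and the rest renormalized the change of Alas1 at this probe was 3.07 (adjusted p = 0.0325), while its other probe changed by -0.14 on the deposited values.

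Among 75 genes with 2 or more called probes, 5 had calls in both directions, namely Gm5858, Larp1, Nipsnap3b, Rpl17 and Sik3. The 7 probes of Rpl17 ranged from -1.97 to 2.11, and those of Gapdh from 0.13 to 1.64. After stained spots were left out and the rest renormalized, 142 genes had 2 or more called probes and 17 had calls in both directions. Gclc, a gene of glutathione synthesis, had 13.83 on a stained spot of control 4 and 8.85 to 9.06 in the other controls, and its change went from 0.59 to 1.73 when stained spots were left out and the rest renormalized.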
